A study of Mus musculus with 20 samples.

How the data were processed

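RNA of 20 mouse libraries was sequenced from stranded poly(A) TruSeq preparations, per the labels' protocols. The deposited files hold raw whole-number counts per gene for 25700 Ensembl mouse gene identifiers, and the authors made them with bcl2fastq 2.19, Trimmomatic, STAR 2.7.1 and featureCounts, with edgeR for testing, per the submitters' processing notes. The notes give the genome build as GRCh38.p5, a human build, while all identifiers are mouse genes, so the build behind the counts is unresolved. They do not state the strand setting of the counting, so counts of overlapping and antisense genes are uncertain. This holds among the named genes for Spp1, Col6a6 and Hk3. Symbols and coordinates were taken from GENCODE M21 (GRCm38), which matched 25587 identifiers and left 113 unmatched, holding at most 0.0541% of the counts of any library. Total counts per library ran from 25547840 to 39550689, and the tests rest on the spread between libraries, not on counting error. Groups were taken from the sample titles and treatment labels, with 5 libraries in each of 4 groups.

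The tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with a minimum count of 10, which left 15430 and removed 10270. The tested genes held at least 99.9% of the counts of each library. Libraries were scaled by TMM, and 1 model with 4 group means was fitted to all 20 libraries by edgeR's robust quasi-likelihood method. The 5 comparisons were oxalate against control without alkali, alkali against untreated in oxalate mice and in control mice, oxalate against control on alkali, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size over the square root of the F statistic. The common biological coefficient of variation was 0.200. The groups, the tests of the 5 comparisons, the gene lists, the panel and a first set of alternatives were fixed before the data were examined. Tests of possible explanations and some alternatives were chosen later, as said where they appear.

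The lists covered tubular injury, proximal tubule, thick ascending limb, distal convoluted tubule, principal cell, intercalated cell, podocyte, endothelial, macrophage and monocyte, neutrophil, T and NK cell, B and plasma cell, and fibroblast and matrix genes. They also covered cytokines and chemokines, inflammasome and NF-kB, complement, interferon response, MHC class II, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, gluconeogenesis, ammoniagenesis and acid-base transport, and calcium, phosphate and oxalate handling. The rest were oxidative stress response, cell cycle, cholesterol synthesis, renin-angiotensin, male-biased and female-biased kidney, immediate early, mitochondrially encoded, red blood cell, adipose and adrenal, urothelium and skeletal muscle genes, 37 in all. Some genes sit on more than 1 list, such as Pvalb, Slc4a1 and Cyp4a14. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. List scores, the mean log2 CPM (prior count 2) over the members, were compared by exact two-sided permutation tests over all splits of the 10 libraries, whose smallest p is 0.00794, and adjusted over all lists and the 4 comparisons of 2 groups. Of these, 17 lists passed adjusted p 0.05 for oxalate without alkali, 14 for oxalate on alkali, 0 for alkali in oxalate mice (9 at unadjusted p under 0.05) and 0 for alkali in control mice (2 at unadjusted p under 0.05). The smallest adjusted p of a score was 0.0379.

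Genes are named by 3 fixed rules. Per comparison, up to 6 higher and 6 lower called genes with the largest change were named if their average log2 CPM was at least 1, all 5 libraries of 1 group lay above all 5 of the other, and their symbol was not that of a predicted gene. Separation was not asked for the interaction. A fixed panel of 24 genes, and per described list up to 4 members with the smallest p, were named too. Other names are said to be chosen after their values were seen. Some genes that these rules name are not reported here.

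The code was tested on simulated counts, in which 67, 67 and 66 genes per comparison were changed 1.5-fold, 2-fold and 4-fold. For alkali in oxalate mice, with 15259 genes, 41.8% of 1.5-fold, 88.1% of 2-fold and 93.9% of 4-fold changes were called. For alkali in control mice, with 15255 genes, these shares were 53.7%, 71.6% and 86.4%, for the interaction (15265 genes) 23.9%, 59.7% and 87.9%, for oxalate without alkali (15274 genes) 35.8%, 80.6% and 89.4%, and for oxalate on alkali (15270 genes) 47.8%, 67.2% and 100%. False calls numbered 5 to 7 per run. The simulated genes varied independently, so this is not the false-call level of the real libraries, where regrouped oxalate libraries called up to 2990 genes. Libraries of a group differed by more than counting noise (chi-square per degree of freedom from 9.09 to 217), which does not show whether each came from a separate animal. The alternatives fixed at that point were RLE scaling, DESeq2, limma-voom with sample weights, no filter, a stricter filter of at least 1 CPM in 5 libraries, fits of only the groups compared, no robust estimation and each library left out in turn. Total-count scaling and a fit without the 6 libraries with Adipoq above 1 CPM were added after the data were seen.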

Results

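Gene expression was measured by stranded poly(A) RNA sequencing in 20 mouse libraries that form 4 groups of 5. The groups were untreated control mice, control mice given alkali therapy, untreated oxalate mice and oxalate mice given alkali therapy. The series describes bicarbonate supplementation as the alkali and crystal nephropathy, kidney damage by crystals, as the disease. The sample labels name neither the tissue nor the time of sampling, and the names of both alkali groups carry the word "late", which the labels do not explain. Total counts per library ranged from 25547840 to 39550689. Transcripts of Kap, an androgen-driven gene of the proximal tubule, took 3.28% ± 0.16 (SD, n = 5) of the counts in untreated controls and 2.14% ± 0.58 (SD, n = 5) in untreated oxalate libraries. The leading principal component held 64.5% of the variance. On it the 10 control libraries lay between -61.9 and -32.0, the untreated oxalate libraries between 26.2 and 102, and the alkali-treated oxalate libraries between -17.0 (replicate 2) and 69.3 (replicate 33). Nothing in the labels says that each library came from a separate animal, so the p-values measure the spread between libraries, which may in part be technical.

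The comparison of untreated oxalate with untreated control libraries addressed what crystal nephropathy changed without alkali. Havcr1 and Lcn2, which injured tubule cells switch on, were far higher in oxalate libraries. So were Vcam1, an adhesion molecule that damaged proximal tubule cells also carry, Ccl2, the chemokine that draws monocytes, and Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages. Aqp4, a basolateral water channel, and Hrg, a plasma glycoprotein gene, were lower. Called genes of the immune, matrix and antigen-presentation lists were nearly all higher, and most called genes of the proximal tubule and mitochondrial metabolism lists were lower. Changes below are log2 fold changes ± SE with n = 5 libraries per group, and genes are ranked by size of change only among called genes with an average log2 CPM of at least 1 and no overlap between the libraries of the groups compared. Havcr1 rose by 4.33 ± 0.47 (edgeR quasi-likelihood test, adjusted p = 1.2e-06), from a mean of 2.65 to 52.9 CPM (counts scaled to library size). Untreated oxalate library 12 had 137 CPM, and without it the oxalate mean was 31.8 CPM and the change 3.59 (adjusted p = 6.86e-07). Gpnmb rose by 10.92 ± 0.98, from 0.252 to 503 CPM, and Lyz1, Mmp7 and Clec4d rose by 7.72 ± 0.72, 7.61 ± 0.90 and 7.54 ± 0.85. The largest decreases were those of Hrg (-2.58 ± 0.49), Col19a1 (-2.54 ± 0.59) and Aqp4 (-2.41 ± 0.32, from 42.5 to 8.01 CPM). In the GRCm38 assembly Havcr1 lies on chromosome 11 from 46735080 to 46779578, Gpnmb on chromosome 6 from 49036546 to 49070929, and Aqp4 on chromosome 18 from 15389496 to 15410982. Of 15430 genes tested, 4067 were higher and 3563 lower, and 2145 and 288 of these changed at least 2-fold. Higher genes made up 53.3% of the called genes. Scaling by total counts in place of TMM (edgeR's trimmed mean of M-values) moved the median of all genes up by 0.30 log2 and gave 7498 higher and 1308 lower genes, 85.1% higher, so directions of small changes are relative to this shift. Single libraries moved some of the changes of this comparison by over 1.5 times, and the following were still called. Without untreated oxalate library 40 Gpnmb was at 10.22, Clec4d at 6.89, Il7r at 5.25 and Slc7a11 at 2.95, without untreated control library 35 Mmp7 was at 8.98, without 13 Clec4d was at 9.46, and without 19 Ccl2 was at 5.23.

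Of the tubular injury list, 23 of 26 tested genes were higher and none was lower, with Lcn2 at 4.78 ± 0.44, Vcam1 at 3.90 ± 0.28 and Cd44, a hyaluronan receptor, at 4.09 ± 0.34. Macrophage and monocyte genes were higher for 23 of 24, among them Lyz2 (5.52 ± 0.45) and Cd68 (4.72 ± 0.52). All 17 T and NK cell genes were higher, such as Il7r, the interleukin 7 receptor (6.01 ± 0.62), and Cd4 (3.32 ± 0.39). All 31 fibroblast and matrix genes were higher, such as Col1a1 (3.19 ± 0.38), Fn1 (3.13 ± 0.33) and Mmp2 (3.30 ± 0.33). Cytokines and chemokines were higher for 24 of 27, with Ccl2 at 4.14 ± 0.55 and Ccl9 at 4.54 ± 0.44, and inflammasome and NF-kB genes for 21 of 22, with Tlr2 at 2.93 ± 0.32. Complement genes were higher for 14 of 18 and lower for 2, with C3 at 3.41 ± 0.44, interferon response genes higher for 22 of 24, with Mx1 at 2.59 ± 0.32, and all 10 MHC class II genes higher, with H2-Ab1 at 2.09 ± 0.19. Neutrophil genes were higher for 4 of 6, with Csf3r at 3.18 ± 0.42. B and plasma cell genes were higher for 7 of 14, with Cd22 at 4.46 ± 0.60. Cell cycle genes were higher for 23 of 26, with Mki67 at 1.77 ± 0.32, and immediate early genes, which cells switch on within minutes of a stimulus, for 12 of 19, with Socs3 at 3.43 ± 0.31. Adjusted over the list alone, 14 immediate early genes were higher and the other counts were the same. The medians of these lists ran from 0.99 (interferon response) to 3.29 (macrophage and monocyte). Camera, which compares a list with all other genes, called each of them, with adjusted p from 4.31e-17 (macrophage and monocyte) to 0.0209 (neutrophil), except B and plasma cells (median 1.31, adjusted p = 0.071, and 0.0360 without alkali-treated oxalate library 33). With an estimated correlation between genes in place of the preset 0.01, none of these calls held: the adjusted p ranged from 0.280 (injury, macrophage, T and NK cell, cytokine, complement and MHC class II lists) to 0.491 (immediate early genes) with an estimated correlation, with adjusted p = 0.288 for NF-kB, 0.341 for matrix, 0.365 for neutrophil and interferon and 0.41 for cell cycle genes. Fry, which tests whether a set's genes move on balance one way and makes no comparison with other genes, gave adjusted p from 3.13e-07 to 0.0165 over all 21 lists that camera called.

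Proximal tubule genes were lower for 28 of 30 (median -0.91, 29 adjusted over the list alone), among them Slc7a13, a cystine and aspartate transporter (-1.76 ± 0.30), Slc27a2, a fatty acid transporter (-1.12 ± 0.22), and the endocytic receptor Lrp2 (-1.22 ± 0.25). All 24 genes of the tricarboxylic acid cycle were lower (median -0.55), such as Mpc1 (-0.74 ± 0.15) and Sucla2 (-0.67 ± 0.13). Oxidative phosphorylation genes were lower for 43 of 70 and higher for none (median -0.32, 44 adjusted over the list alone), for example Cycs at -0.68 ± 0.14 and Sdha at -0.60 ± 0.13. Fatty acid oxidation genes were lower for 24 of 36 and higher for 3 (median -0.48, 25 lower adjusted over the list alone), with Etfa at -0.75 ± 0.15 and Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, at -0.49 ± 0.12. Under total-count scaling the medians of these 4 lists stayed below 0, with 23, 19, 9 and 15 genes lower. Gluconeogenesis genes were lower for 7 of 10 and higher for 1 (median -0.73), male-biased kidney genes lower for 9 of 12 (median -0.96, 10 adjusted over the list alone) and genes of the renin-angiotensin system lower for 6 of 9 (median -0.57). Examples were Gk (-1.12 ± 0.23), Cyp4a12a (-2.14 ± 0.45) and Agtr1a (-0.57 ± 0.08). Camera called these 7 lists with adjusted p of 9.89e-10, 9.3e-10, 9.3e-10, 4.07e-06, 0.0119, 0.000345 and 0.00763 in that order. With an estimated correlation the adjusted p was 0.373, 0.365, 0.491, 0.485, 0.491, 0.373 and 0.341. Podocyte genes were higher for 10 of 15 (median 0.45, 11 adjusted over the list alone), with Ptpro at 0.97 ± 0.13 and Synpo at 0.73 ± 0.12 (camera adjusted p = 0.000641, and adjusted p = 0.341 with an estimated correlation). Cholesterol synthesis genes were lower for 12 of 24 and higher for 3, with Hmgcs1 at -0.79 ± 0.16, and their median of -0.26 changed sign to 0.04 under total-count scaling, with 8 genes higher and 3 lower. Camera called them lower (adjusted p = 0.0209, and adjusted p = 0.491 with an estimated correlation), a call lost without untreated control library 19 (0.0635).

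Camera called none of the remaining lists. Thick ascending limb, distal convoluted tubule and intercalated cell genes went both ways (2 higher and 2 lower of 15, 2 and 2 of 13, and 2 and 1 of 15), and their medians of -0.11, -0.11 and -0.03 changed sign to 0.22, 0.18 and 0.25 under total-count scaling, while the mean of the intercalated cell list was 0.13. Among them Cldn16 (0.80 ± 0.13), Trpv5 (1.04 ± 0.15) and Atp6v0d2 (1.23 ± 0.22) rose, Egf (-0.91 ± 0.22) and Cldn10 (-0.77 ± 0.11) fell, and Umod was not called (-0.05 ± 0.14). Principal cell genes were higher for 5 of 13, with the sodium channel subunit Scnn1g at 0.57 ± 0.14, and Aqp4 alone was lower. In the ammoniagenesis and acid-base transport list 3 of 32 genes were higher and 10 lower, with a median of -0.18 that became 0.11 under total-count scaling. Slc38a1 (1.71 ± 0.21) and Slc9a3, the apical sodium-proton exchanger (-0.83 ± 0.14), changed most clearly, while Pck1 (-0.23 ± 0.26) and Slc38a3 (0.44 ± 0.20) were not called, the latter called without untreated control library 19 (adjusted p = 0.0354) or untreated oxalate library 32 (adjusted p = 0.0429). Camera gave this list adjusted p = 0.073, which fell under the threshold without untreated oxalate library 3 (0.0419) or 39 (0.0215). Calcium, phosphate and oxalate handling genes were higher for 8 of 26 and lower for 10, with Mgp, an inhibitor of calcification, and the calcium channel gene Trpv6 higher, the latter at 1.82 ± 0.24, and Kl at -0.65 ± 0.13. Glycolysis genes were higher for 5 of 20 and lower for 8, with Hk3, a hexokinase of myeloid cells that overlaps another gene, at 5.11 ± 0.54. Their median (0.01) and mean (0.50) were above 0, while camera placed them lower (adjusted p = 0.995). Oxidative stress genes were higher for 5 of 23 and lower for 7, with Slc7a11 at 3.69 ± 0.50 and Gclm at -0.77 ± 0.16. Their median of -0.28 and mean of 0.06 differed in sign, and under total-count scaling the median became 0.01. Female-biased genes were higher for 3 of 10 and lower for 3, with a median of -0.10, a mean of 0.20 and a median of 0.19 under total-count scaling. Mitochondrially encoded genes were lower for 7 of 10 (median -0.51, camera adjusted p = 0.073), and 2 were lower under total-count scaling. Red blood cell genes were lower for 2 of 8 (median -0.52), with camera adjusted p = 0.08 that fell to 0.0248 without untreated control library 9 and to 0.0285 without untreated oxalate library 39. Endothelial genes were higher for 3 of 15, urothelium genes for 2 of 10, skeletal muscle genes for 1 of 3, and adipose and adrenal genes lower for 1 of 6. Adjusted over the list alone these counts were 0, 0, 1 with 1 lower, and 0. The skeletal muscle median of -0.29 and mean of 0.50 differed in sign. Under total-count scaling camera called the mitochondrially encoded (0.000865), ammoniagenesis (0.0264), red blood cell (0.0159) and adipose and adrenal lists (0.0195) lower, and the neutrophil call was lost (0.129). With TMM, fry called 4 lists that camera did not: mitochondrially encoded (0.00243) and red blood cell genes (0.0426) lower, and B and plasma cell (0.0159) and calcium, phosphate and oxalate handling genes (0.0132) higher. Without the 6 libraries with Adipoq, a fat-cell gene, above 1 CPM the urothelium list was called higher (0.0311).

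**Figure D1:**
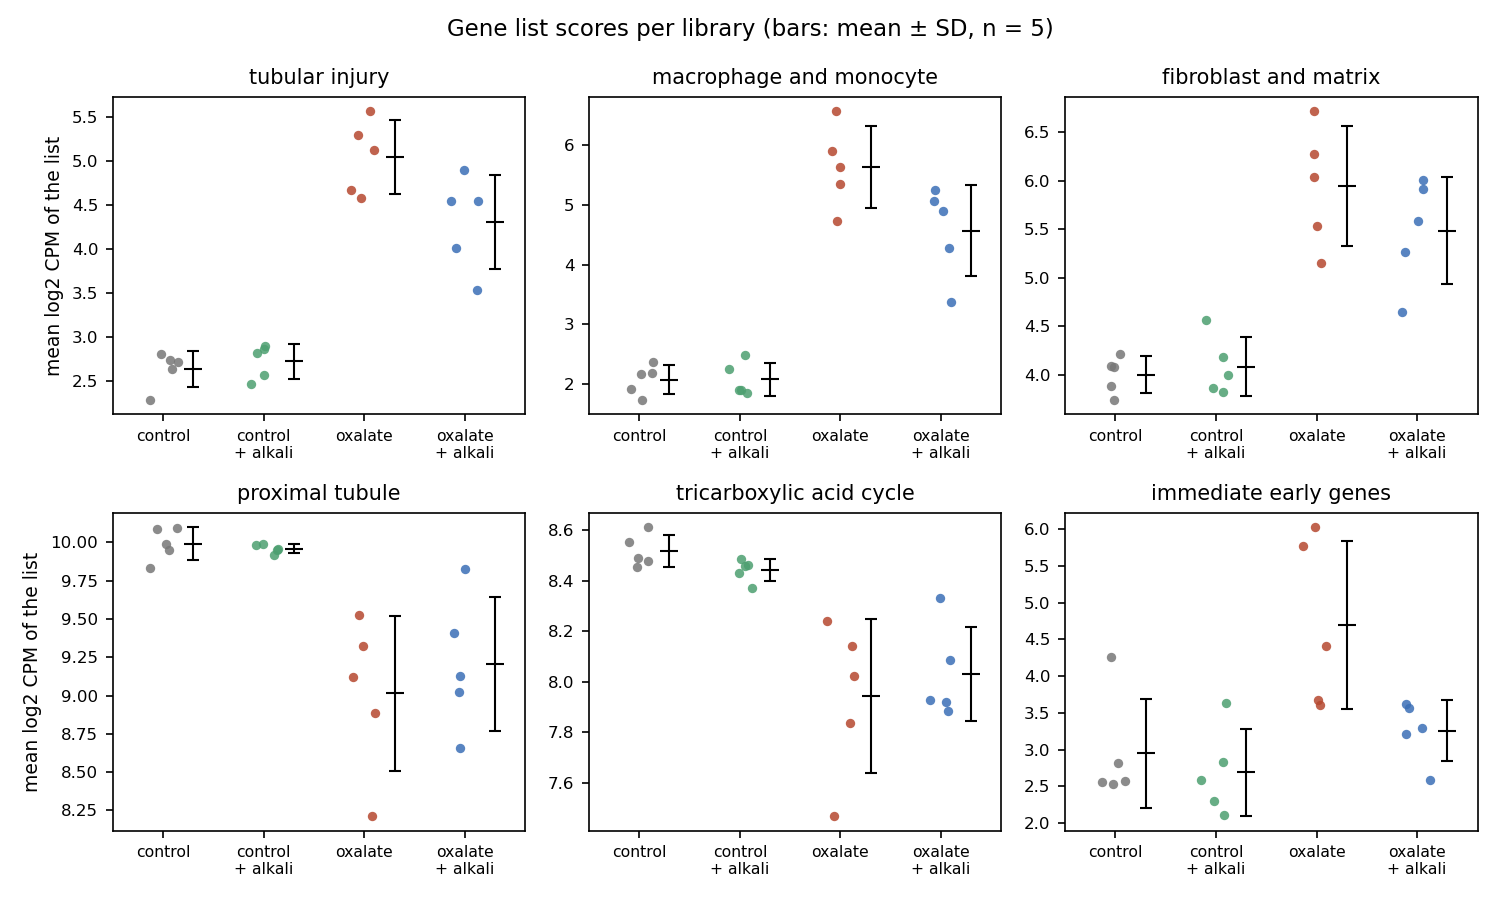
Mean log2 CPM of 6 gene lists (y axis) in the 4 groups of 5 libraries (x axis), with a point per library and bars for mean ± SD. The tubular injury score was 2.63 ± 0.21 in untreated controls, 5.05 ± 0.42 in untreated oxalate libraries and 4.30 ± 0.54 in alkali-treated oxalate libraries, and the proximal tubule score was 9.99 ± 0.11, 9.01 ± 0.51 and 9.21 ± 0.44.

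The comparison of alkali-treated with untreated oxalate libraries addressed what alkali changed in diseased mice. Some genes of tubular injury and inflammation were lower with alkali. They included Havcr1, Vcam1, Sox9, a transcription factor of regenerating tubule cells, and the neutrophil chemokine Cxcl2. Slc38a3, the glutamine transporter that feeds renal ammonia production, and Pck1, the rate-limiting enzyme of gluconeogenesis, were lower too. Slc4a1, whose kidney form returns bicarbonate to the blood from acid-secreting intercalated cells, and the anti-ageing hormone gene Kl were higher. Aqp4, lowered by oxalate, was higher with alkali. Within the limits on level and overlap given above, the largest increases were those of Ces1g, a lipid-metabolising carboxylesterase (2.39 ± 0.31, from 29.7 to 156 CPM, adjusted p = 0.000766), Col6a6 (1.82 ± 0.30, a gene that overlaps another) and Aqp4 (1.44 ± 0.31). Among the largest decreases were those of Cyp4a14, a fatty acid hydroxylase driven by PPAR-alpha (-4.64 ± 0.91, from 315 to 12.6 CPM), the immediate early gene Fosb (-4.32 ± 1.03) and Cxcl1 (-3.07 ± 0.64). Slc38a3 fell by 1.34 ± 0.21, from 62.0 to 24.5 CPM (adjusted p = 0.0031), and Pck1 by 1.57 ± 0.26, from 1.91e+03 to 643 CPM (adjusted p = 0.0041). Slc4a1 rose by 0.95 ± 0.16, from 35.6 to 68.5 CPM (adjusted p = 0.00424), and Kl by 0.59 ± 0.13. In GRCm38 these lie on chromosome 9 from 107650634 to 107669530 (Slc38a3), chromosome 2 from 173153048 to 173159273 (Pck1) and chromosome 11 from 102348824 to 102366203 (Slc4a1). In all, 271 genes were higher and 359 lower, 47 and 151 of them at least 2-fold. The counts depended on single libraries: 93 and 92 without untreated oxalate library 12, 167 and 182 without 3, 442 and 718 without 32, 204 and 211 without 40, 112 and 92 without alkali-treated oxalate library 30, 411 and 563 without 33, and 169 and 210 without 8. Without untreated oxalate library 12 the calls of Aqp4, Cxcl1, Kl and Fosb were lost (adjusted p = 0.0552, 0.0512, 0.0612 and 0.0671), with Cxcl1 at -2.25, and that of Fosb was also lost without untreated oxalate library 3 or alkali-treated oxalate library 2, 30, 5 or 8 (adjusted p from 0.0516 to 0.0723), with Fosb at -3.57 without 3. The main fit estimates 1 spread per gene over all 20 libraries, controls included. A fit of the 10 oxalate libraries alone called 15 higher and 14 lower, 27 of them among the 630. It kept 6 of 58 named calls (Ces1g, Cyp4a14, Slc38a3, Trpm6, Gsta2 and Agtr1a), and among those lost were Havcr1 (0.0999), Vcam1 (0.0628), Sox9 (0.125), Cxcl2 (0.0603), Pck1 (0.0688), Slc4a1 (0.0693), Kl (0.181), Aqp4 (0.0995), Col6a6 (0.0756), Fosb (0.1) and Cxcl1 (0.0617).

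Tubular injury genes were lower for 8 of 26 (median -0.53, 15 adjusted over the list alone), with Havcr1 at -1.95 ± 0.41 (-1.21 without untreated oxalate library 12, adjusted p = 0.0374), Vcam1 at -1.42 ± 0.25, Sox9 at -2.02 ± 0.41 and Cd44 at -1.38 ± 0.29, while Lcn2 (-0.61 ± 0.36) and Spp1 (-0.53 ± 0.21, a gene that overlaps another) were not called, Spp1 being called without alkali-treated oxalate library 33 (adjusted p = 0.0361). Macrophage and monocyte genes were lower for 9 of 24 (median -1.02, 21 adjusted over the list alone), with Lgals3 at -1.35 ± 0.26, and Cd68 was not called (-1.53 ± 0.44) except without untreated oxalate library 32 or 39 or alkali-treated oxalate library 8 (adjusted p = 0.015, 0.0498 and 0.0466). Cytokines and chemokines were lower for 9 of 27 (median -0.86, 14 adjusted over the list alone), with Cxcl2 at -2.59 ± 0.51 and Ccl2 at -2.28 ± 0.49, whose call was lost without untreated oxalate library 12 (adjusted p = 0.0567). Inflammasome and NF-kB genes were lower for 6 of 22 (median -0.70, 16 adjusted over the list alone), and immediate early genes for 6 of 19 (median -1.35, 17 adjusted over the list alone), with Klf6 at -1.16 ± 0.24. These 5 lists were called lower by camera, with adjusted p of 1.35e-09, 1.21e-12, 3.96e-10, 1.35e-09 and 1.35e-09. With an estimated correlation each had adjusted p = 0.385. Fry gave 0.0406, 0.0406, 0.0388, 0.0406 and 0.0454. Of the fibroblast and matrix genes 1 of 31 was lower, Vim at -1.01 ± 0.28, and neither Col1a1 (-0.67 ± 0.35) nor Fn1 (-0.65 ± 0.30) was called. Camera placed that list (median -0.44), complement (1 of 18 lower, 7 adjusted over the list alone) and MHC class II genes (0 called, 8 lower adjusted over the list alone) lower, with adjusted p of 9.19e-06, 0.000892 and 0.0002 and of 0.536, 0.445 and 0.445 with an estimated correlation. Fry lost these 3 (0.23, 0.0923 and 0.0923). The call of Vim was lost without each library (adjusted p from 0.0511 to 0.129) other than untreated controls 19 and 26, alkali-treated control 4, untreated oxalate libraries 32 and 39 and alkali-treated oxalate libraries 33 and 8.

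Camera also placed lower the T and NK cell list (1 of 17 lower, Il7r at -2.01 ± 0.47, whose call was lost without untreated oxalate library 12 (adjusted p = 0.0507) or 40 (-1.29, 0.0752) or alkali-treated oxalate library 30 (0.0705)), interferon response genes (0 called, 2 lower adjusted over the list alone) and neutrophil genes (0 called, 1 lower adjusted over the list alone). Cell cycle genes (0 called), cholesterol synthesis genes (0 called) and oxidative stress genes (3 of 23 lower, 4 adjusted over the list alone) were placed lower too. Among the last, the glutathione transferase Gsta2 fell by 1.30 ± 0.13. The adjusted p was 0.000621, 0.0002, 0.0108, 0.0136, 0.0113 and 0.00673 in that order, and with an estimated correlation it was 0.515, 0.536, 0.406, 0.759, 0.515 and 0.536. Fry gave 0.147, 0.194, 0.0488, 0.461, 0.18 and 0.168, so only the neutrophil call held there. Genes of the distal nephron were placed higher: distal convoluted tubule (3 of 13 higher, 8 adjusted over the list alone, median 0.35), thick ascending limb (2 of 15, 4 adjusted over the list alone, median 0.31), intercalated cell (2 of 15, median 0.30) and principal cell (1 of 13, median 0.18). Their adjusted p was 1.42e-06, 0.000273, 0.000193 and 0.00938, and 0.385, 0.385, 0.406 and 0.515 with an estimated correlation, and fry gave 0.0388, 0.0406, 0.0618 and 0.194. Proximal tubule (1 of 30, median 0.20), endothelial (1 of 15, Kdr at 0.36 ± 0.07), tricarboxylic acid cycle (0 of 24, median 0.07), renin-angiotensin (2 of 9, 3 adjusted over the list alone) and mitochondrially encoded genes (0 of 10, 6 adjusted over the list alone) were placed higher as well. Their adjusted p was 0.00938, 0.00257, 0.03, 0.046 and 0.0429, and 0.759, 0.515, 0.759, 0.515 and 0.548 with an estimated correlation. Fry gave 0.526, 0.18, 0.569, 0.128 and 0.0488. In the renin-angiotensin list the angiotensin receptor gene Agtr1a rose by 0.49 ± 0.08, and the list's median of 0.03 changed sign under total-count scaling. Many of these calls hung on single libraries. Without untreated oxalate library 40 the adjusted p rose to 0.775 for proximal tubule, 0.061 for principal cell, 0.061 for neutrophil, 0.294 for cell cycle, 0.191 for renin-angiotensin and 0.0719 for mitochondrially encoded genes, and the tricarboxylic acid cycle list gave 0.895 in the other direction. Without alkali-treated oxalate library 2 it rose to 0.521, 0.105, 0.0904, 0.545, 0.525, 0.292 and 0.0933 for the proximal tubule, T and NK cell, interferon, tricarboxylic acid cycle, cell cycle, renin-angiotensin and mitochondrially encoded lists. Without untreated oxalate library 12 the tricarboxylic acid cycle, renin-angiotensin and mitochondrially encoded lists gave 0.122, 0.0615 and 0.154, and without 32 the endothelial, oxidative stress and renin-angiotensin lists gave 0.0527, 0.0527 and 0.0513. Without alkali-treated oxalate library 33 oxidative stress gave 0.112 and mitochondrially encoded genes 0.108, without 8 principal cell, cholesterol and mitochondrially encoded genes gave 0.0826, 0.0589 and 0.0532, and without 5 cholesterol gave 0.0549. Without untreated control library 13 renin-angiotensin and mitochondrially encoded genes gave 0.0525 and 0.0528, and without 26 renin-angiotensin gave 0.0514. Without the 6 libraries with Adipoq above 1 CPM the endothelial (0.16), oxidative stress (0.398) and mitochondrially encoded calls (0.0831) were lost, while oxidative phosphorylation (0.00551) and male-biased genes (0.0293) were called higher and urothelium genes (0.0492) lower.

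The other lists were not called for alkali in oxalate mice. In the ammoniagenesis and acid-base list Slc4a1 was higher and Slc38a3 and Pck1 lower, 2 and 2 adjusted over the list alone, and the list passed the threshold without untreated oxalate library 39 (0.038). Calcium, phosphate and oxalate handling genes were higher for 3 of 26 and lower for 2, including Cyp27b1, which makes active vitamin D (-1.92 ± 0.44, not called without alkali-treated oxalate library 30, adjusted p = 0.0633). Fatty acid oxidation genes were lower for 2 of 36 (4 adjusted over the list alone), glycolysis genes for 1 of 20 (Hk3, adjusted p = 0.0507 without alkali-treated oxalate library 30; 2 adjusted over the list alone) and oxidative phosphorylation genes for 0 of 70. Their medians of 0.01, 0.04 and 0.01 changed sign under total-count scaling, and their means of -0.17, -0.19 and -0.02 were below 0, with camera placing the glycolysis list higher (adjusted p = 0.713). Without untreated oxalate library 40 camera placed oxidative phosphorylation (0.000291) and fatty acid oxidation (0.00161) lower, and gluconeogenesis gave 0.017. Without untreated oxalate library 32 oxidative phosphorylation gave 0.02. B and plasma cell genes (0 of 14, 1 adjusted over the list alone) gave 0.0367 and 0.0333 without alkali-treated oxalate libraries 2 and 8. Gluconeogenesis (1 of 10 lower), podocyte (0 of 15), male-biased (0 of 12), female-biased (2 of 10 lower, 1 higher adjusted over the list alone), red blood cell (1 of 8 higher), adipose and adrenal (0 of 6), urothelium (0 of 10) and skeletal muscle genes (1 of 3 higher) gave camera adjusted p of 0.522, 0.895, 0.419, 0.513, 0.619, 0.713, 0.515 and 0.144, while fry placed skeletal muscle genes higher (0.0406). Podocyte and female-biased medians changed sign under total-count scaling. Median and mean differed in sign for podocyte (0.03 and -0.02), calcium (0.09 and -0.03) and red blood cell genes (-0.05 and 0.04).

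**Figure D2:**
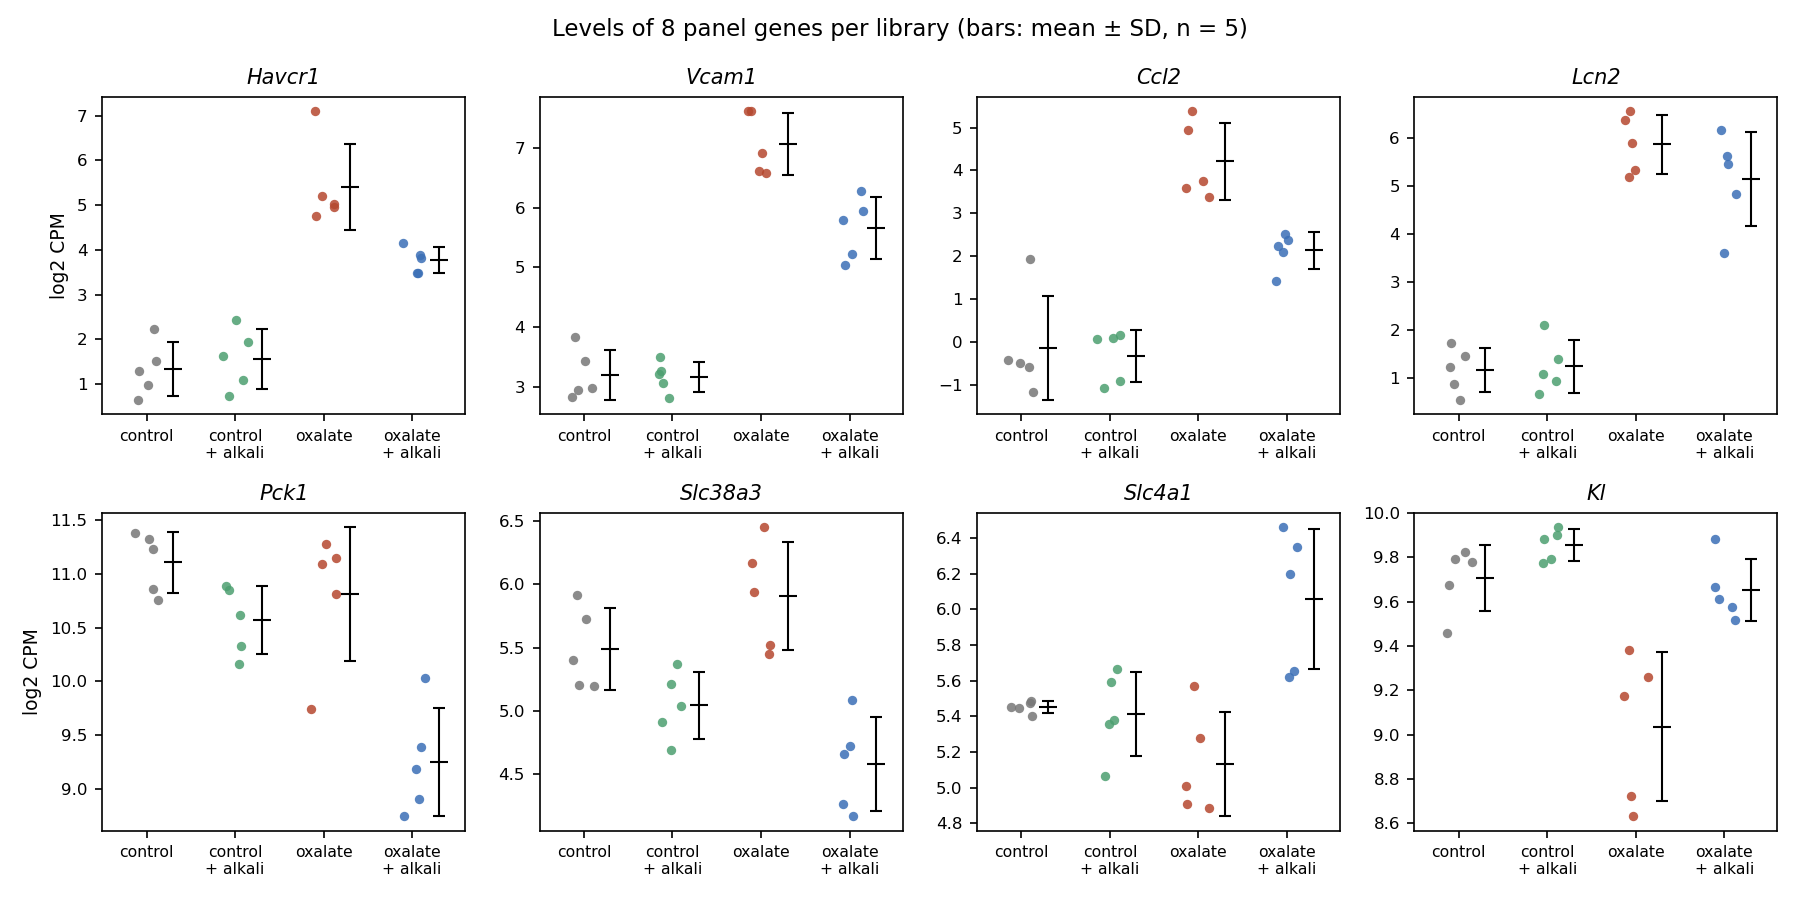
Log2 CPM (y axis) of 8 genes in the 4 groups of 5 libraries (x axis), with a point per library and bars for mean ± SD. Havcr1, Vcam1 and Ccl2 rose with oxalate by 4.33, 3.90 and 4.14 and were lower with alkali by log2 changes of -1.95, -1.42 and -2.28, while Slc4a1 was at 0.95 with alkali in oxalate libraries and at -0.03 in controls, where it was not called, and the difference was not called either.

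The comparison of alkali-treated with untreated control libraries addressed what alkali changed in mice without crystals. Atp12a, the proton-potassium pump of the collecting duct, came closest to a call. Next by p among the list members, though not among all genes, were Insig1, which restrains sterol synthesis, and Trpm6, the magnesium channel of the distal convoluted tubule. Camera alone placed cholesterol synthesis genes lower and distal convoluted tubule and cell cycle genes higher, and these calls held neither with an estimated correlation nor with fry. The injury markers were not called. EdgeR's quasi-likelihood test called 0 genes, with 389 at unadjusted p under 0.05. Limma-voom called 0 (1071 at unadjusted p under 0.05), and DESeq2 called 3 higher: Atp12a, F2, which encodes prothrombin, and Creb3l3, a transcription factor of lipid metabolism, of which F2 and Creb3l3 are named after their values were seen. Atp12a had a log2 change of 1.89 ± 0.30 (0.72 to 2.67 CPM, adjusted p = 0.0642), and was called without alkali-treated control library 1 (adjusted p = 0.0144) or untreated oxalate library 12 (adjusted p = 0.0394). Without untreated control library 9 the predicted gene Gm2115, named after its value was seen, was called instead (adjusted p = 0.0401). Trpm6 was at 0.50 ± 0.15 and Insig1 at -0.74 ± 0.18. Adjusted over the list alone each of these 3 was called, and they were the only list members so called. Slc38a3 (-0.46 ± 0.20), Pck1 (-0.53 ± 0.26), Havcr1 (0.26 ± 0.46), Vcam1 (-0.07 ± 0.27) and Slc4a1 (-0.03 ± 0.16) were not called. Camera called the distal convoluted tubule (median 0.08, adjusted p = 0.000215) and cell cycle lists (median 0.22, 0.00277) higher, and the cholesterol synthesis (median -0.14, 2.26e-06) and tricarboxylic acid cycle lists (median -0.07, 0.00473) lower. With an estimated correlation the adjusted p was 0.975 for all 4, and fry gave 0.987. The cell cycle call was lost without untreated control library 19 (0.11) or 9 (0.0712) or alkali-treated control library 27 (0.392), and the tricarboxylic acid cycle call without untreated control library 35 (0.157) or alkali-treated control library 4 (0.111). Of the other 33 lists, 10 passed the threshold without 1 library: principal cell (0.00915 without untreated control 26, 0.0116 without alkali-treated control 4), endothelial (0.0349 without untreated control 13), T and NK cell (0.0264 without 26), MHC class II (0.0168 without 26, 0.0491 without alkali-treated control 1) and oxidative stress genes (0.0168 without 26). Oxidative phosphorylation did so without untreated controls 13 and 26 and alkali-treated controls 37 and 7 (0.0349, 0.00915, 0.00539 and 0.0235), immediate early genes without untreated controls 13 and 26 and alkali-treated control 27 (0.0366, 0.0128 and 0.000185) and urothelium without 26 and 27 (0.000117 and 0.0109). Red blood cell and adipose genes did so without alkali-treated control 1 (0.0309) and untreated control 13 (0.0498). Without the 6 libraries with Adipoq above 1 CPM, 9 further lists were called. Principal cell (0.000509) and urothelium genes (0.0008) were higher, and MHC class II (0.0008), cytokine (0.00944), T and NK cell (0.0249), immediate early (0.0249), macrophage (0.0326), NF-kB (0.0436) and B and plasma cell genes (0.0436) lower. Fry there gave each 0.946. Under total-count scaling the cell cycle call was lost (0.0629) and immediate early genes were called lower (0.0352).

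**Figure D3:**
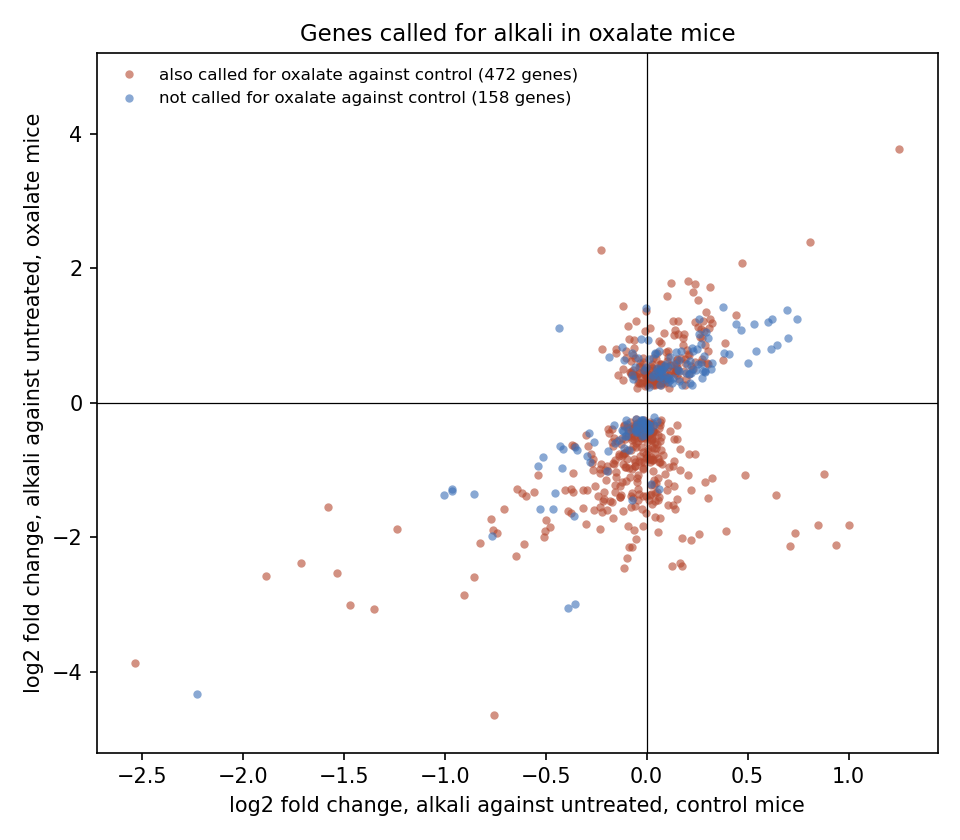
Log2 fold change of alkali against untreated in control mice (x axis) and in oxalate mice (y axis) for the 630 genes called in oxalate mice, with red points for 472 genes that were also called for oxalate and blue points for the other 158. Of the 158 blue points, 135 lie on the same side of 0 on both axes, though their choice used the untreated controls that also enter the x axis.

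The comparison of oxalate with control libraries on alkali addressed which disease changes were present under treatment. Immune and matrix genes were again higher, with Gpnmb, the metalloproteinase gene Mmp7 and the epithelial mucin gene Muc4 among the largest increases. Hpd, of tyrosine breakdown, Etnppl, a lipid-related lyase gene, and Pck1 were among the largest decreases. Lcn2 and Havcr1 were higher here too. Kl, Ppargc1a, the coactivator of mitochondrial genes, and Ren1, the renin gene, were not called here. Gpnmb rose by 8.36 ± 0.91, Mmp7 by 6.16 ± 0.80 (6.81 without alkali-treated control library 7), Gabrp by 5.51 ± 0.58 and Muc4 by 5.42 ± 0.97, while Hpd changed by -2.01 ± 0.39, Ceacam2 by -1.51 ± 0.32, Etnppl by -1.46 ± 0.32 and Pck1 by -1.27 ± 0.26. Havcr1 was at 2.12 ± 0.44, Lcn2 at 4.07 ± 0.43, Vcam1 at 2.55 ± 0.27, Col1a1 at 2.14 ± 0.37 and Slc4a1 at 0.67 ± 0.16, and Kl (-0.20 ± 0.13), Ppargc1a (-0.12 ± 0.11) and Ren1 (0.25 ± 0.20) were not called. In all, 3604 genes were higher and 2633 lower (57.8% higher), 1674 and 54 at least 2-fold. Scaling by total counts moved the median of all genes up by 0.24 log2 and gave 5645 and 953 (85.6% higher). Lower genes numbered 1586 without alkali-treated oxalate library 33 and 1540 without 8. With the untreated fit 2969 genes were higher in both comparisons, where independent lists would share 950, and 2030 were lower in both, against 608. Called in opposite directions were 3 genes, Atp8b5, Gpr85 and Pdxk, named after their values were seen. Of the 7630 genes called without alkali 84.8% changed less on alkali, of the 6237 called on alkali 61.7%, and of all genes 62.6%, the choice of genes favouring the comparison that called them. These shares were computed after the results were seen.

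On alkali, oxalate libraries had higher injury (21 of 26), macrophage and monocyte (22 of 24), T and NK cell (16 of 17), B and plasma cell (8 of 14), fibroblast and matrix (28 of 31), cytokine (22 of 27), NF-kB (18 of 22) and complement genes (14 of 18, 1 lower). Interferon (20 of 24), MHC class II (10 of 10), cell cycle (17 of 26), podocyte (10 of 15) and endothelial genes (10 of 15) were higher as well. Camera adjusted p ran from 6.15e-16 (macrophage) to 0.0029 (B and plasma cell), and from 0.307 to 0.458 with an estimated correlation. Proximal tubule (23 of 30), oxidative phosphorylation (37 of 70), tricarboxylic acid cycle (19 of 24), fatty acid oxidation (27 of 36), gluconeogenesis (8 of 10), cholesterol synthesis (13 of 24, 1 higher), oxidative stress (9 of 23, 2 higher), renin-angiotensin (5 of 9) and male-biased genes (7 of 12) were lower, and oxidative phosphorylation kept 15 of its lower calls under total-count scaling. Their camera adjusted p ran from 2.74e-11 (oxidative phosphorylation) to 0.0153 (renin-angiotensin), and from 0.36 to 0.457 with an estimated correlation. Principal cell (6 higher and 1 lower of 13, 0.0473) and intercalated cell genes (6 and 1 of 15, 0.0312) were placed higher and red blood cell genes lower (2 of 8, 5 adjusted over the list alone, 0.0457). With an estimated correlation these gave adjusted p of 0.486, 0.486 and 0.457. Fry kept the calls of these 25 lists (adjusted p from 4.21e-05 to 0.0353) except that of red blood cell genes (0.0521), and also called neutrophil (0.00759), calcium (0.0332) and skeletal muscle genes (0.0361) higher. Adjusted over the list alone, counts moved most for oxidative phosphorylation (45 lower), tricarboxylic acid cycle (22 lower), cell cycle (20 higher) and ammoniagenesis genes (6 higher), and the other counts by at most 2. The principal cell call was lost without untreated controls 19, 35 and 9, alkali-treated controls 1 and 4, untreated oxalate libraries 32 and 40 or alkali-treated oxalate libraries 33, 5 and 8 (0.0501 to 0.136). The intercalated cell call was lost without alkali-treated controls 27 and 4 or alkali-treated oxalate libraries 5 and 8 (0.0522 to 0.0631), and the red blood cell call without alkali-treated controls 37, 4 and 7, untreated oxalate libraries 32 and 40 or alkali-treated oxalate libraries 2 and 5 (0.0573 to 0.089). Not called were thick ascending limb (3 and 2 of 15), distal convoluted tubule (2 of 13 higher), ammoniagenesis (3 and 10 of 32) and calcium, phosphate and oxalate genes (7 and 3 of 26), glycolysis (7 and 5 of 20) and female-biased genes (2 and 3 of 10). Neither were immediate early (3 of 19 higher), neutrophil (2 of 6 higher, and 0.0495 without alkali-treated oxalate library 30), mitochondrially encoded (1 of 10 lower), adipose and adrenal (0 of 6), urothelium (0 of 10) and skeletal muscle genes (1 of 3 higher). The medians of the ammoniagenesis (-0.10), calcium (-0.05) and mitochondrially encoded lists (-0.04) became 0.12, 0.15 and 0.18 under total-count scaling, and the calcium list's mean was 0.21. Camera placed the adipose and adrenal list lower (adjusted p = 0.564), against its median of 0.71. Without the 6 libraries with Adipoq above 1 CPM the principal cell (0.272), intercalated cell (0.0773) and renin-angiotensin calls (0.0546) were lost.

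The interaction asked whether the alkali change differed between oxalate and control mice. Among the panel and list genes, those with the smallest p were led by Gsta2, Aldh1a1, which makes retinoic acid, Slc4a1, Vcam1 and Havcr1, all with a larger alkali change in oxalate mice. EdgeR's quasi-likelihood test called 0 genes, with 1429 at unadjusted p under 0.05 and a smallest adjusted p of 0.0907. DESeq2 called 12 higher and 14 lower, and limma-voom called 1 lower, Gsta2. Without alkali-treated control library 4, 2 genes were called higher (F2 and Nccrp1) and 1 lower (Eif1a), and without untreated oxalate library 3, 1 was called higher (F2). F2, Nccrp1 and Eif1a are named after their values were seen. The differences were -0.89 ± 0.18 for Gsta2, -1.24 ± 0.28 for Aldh1a1, 0.97 ± 0.22 for Slc4a1, -1.35 ± 0.37 for Vcam1 and -2.21 ± 0.61 for Havcr1. Adjusted over the list alone, 4 injury, 3 cytokine, 2 female-biased, 1 ammoniagenesis and 1 oxidative stress gene had a more negative alkali change in oxalate mice. There, 2 renin-angiotensin genes and 1 each of the ammoniagenesis, principal cell, intercalated cell and endothelial lists had a more positive one. Camera called 19 lists, and with an estimated correlation none held (adjusted p from 0.653 to 0.708 with an estimated correlation). Without the 6 libraries with Adipoq above 1 CPM the MHC class II (0.0671), oxidative stress (0.71) and mitochondrially encoded calls (0.14) were lost. Neutrophil (0.0111) and urothelium genes (0.000791) were then called lower, and oxidative phosphorylation (0.00843), ammoniagenesis (0.0436), renin-angiotensin (0.0283) and male-biased genes (0.0314) higher. Under total-count scaling the T and NK cell call was lost (0.0674), and B and plasma cell (0.0463) and male-biased genes (0.0297) were called higher. Lists not called with all libraries that passed the threshold without 1 library were principal cell (0.00792 without alkali-treated oxalate 2), fatty acid oxidation (0.00307 without untreated oxalate 40), ammoniagenesis (0.0207 without untreated oxalate 39) and neutrophil genes (0.0219 without untreated control 19, 0.0255 without untreated oxalate 32). Oxidative phosphorylation did so without untreated oxalate 32, 39 and 40 (0.00235, 0.00895 and, in the other direction, 0.0216), and B and plasma cell genes without alkali-treated control 1 and alkali-treated oxalate 2 and 8 (0.0338, 0.0387 and 0.0395). Male-biased genes did so without untreated oxalate 32 and alkali-treated oxalate 33 and 8 (0.0315, 0.0237 and 0.0472), and urothelium genes without untreated control 26, alkali-treated control 27, untreated oxalate 12 and alkali-treated oxalate 33 (0.0039, 0.0308, 0.0148 and 0.0096). A call missed in controls and made in oxalate mice is thus not shown to be a difference between them for any single gene in the quasi-likelihood test.

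The genes raised by oxalate and lowered by alkali included Havcr1, Vcam1, Ccl2 and Lgals3, and those lowered by oxalate and raised by alkali included Aqp4 and Kl. Of the 630 genes called for alkali in oxalate mice, 469 had been called the other way for oxalate, 3 the same way and 158 not at all. The 3 genes were Lamtor5, Hebp1 and Slc6a20a, lower in both comparisons and named after their values were seen. Higher then lower were 289 genes, where independent lists would share 94.6, and lower then higher were 180, against 62.6. The untreated oxalate libraries enter both comparisons with opposite signs, so chance alone gives opposite changes. Across genes, which are not independent replicates, the correlation of the changes was -0.657, against -0.494 in simulated unchanged groups. The covariance was -0.257, against -0.0304. The simulated covariance ran only from -0.0361 to -0.0281, so those groups held little variation that genes share between libraries. They do not show what uneven injury between the groups would give. With the 5 untreated oxalate libraries split between the comparisons in all 20 ways, the covariance had a median of -0.257 and ran from -0.379 to -0.0201, and the opposite calls had a median of 78.5 and ran from 2 to 1456. Opposite calls numbered 135 without untreated oxalate library 12, 261 without 3, 978 without 32, 240 without 40, 272 without alkali-treated oxalate library 2, 147 without 30, 786 without 33 and 298 without 8. Genes that moved the same way numbered 1 without untreated oxalate library 12 or 3 or alkali-treated oxalate library 30, 5 or 8, and 47 without alkali-treated oxalate library 2.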

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

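The test of the covariance without shared libraries, the test of uneven injury between 2 groups of 5 mice, the test over splits of the control libraries and the test of TMM scaling were chosen after their results or an earlier form of them were seen, and total-count scaling and the fit without 6 adipose-rich libraries were added later too.

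Some libraries stood apart from the other 4 of their group in markers of other tissues, in stress genes or in injury genes. The highest or lowest value lay away from the rest by more than 0.71 of the group's range in 15 of 268 groups of 5, where chance gives about 1 in 20. The count is thus close to that of chance, and any single value below may be a chance one. Adipose and adrenal genes scored 2.44 in untreated oxalate library 32 (others -1.05 to -0.79) and 5.07 in alkali-treated oxalate library 33 (others -1.34 to -1.08). Adipoq, the fat-cell hormone gene, reached 35.4 CPM in the latter and 29.7 CPM in untreated control library 26. Untreated control library 19 scored 0.77 for cytokines and chemokines (others 0.23 to 0.35) and 4.27 for immediate early genes (others 2.53 to 2.81), with Ccl2 at a log2 CPM of 1.94 (others -1.18 to -0.43). Havcr1 was at 7.10 in untreated oxalate library 12 (lowest of the others 4.75) and C3 at 5.77 in untreated control library 26 (others 3.97 to 4.29). Alkali-treated control library 4 scored 3.37 for interferon response (others 2.84 to 2.97) and had Ren1 at 6.61 (others 6.19 to 6.31) and a TMM factor of 0.967 (others 0.915 to 0.921). The remaining values were oxidative stress at 7.60 in untreated oxalate library 40 (others 8.07 to 8.12), cell cycle at 1.79 in untreated control library 35 (others 1.06 to 1.24), red blood cell at 4.46 in untreated oxalate library 39 (others 3.54 to 3.76), Ppargc1a at 6.62 in untreated control library 13 (others 6.35 to 6.41) and Glud1 at 8.54 in alkali-treated oxalate library 2 (others 8.02 to 8.16). No biological explanation was tested for these.

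Camera placed the difference between the alkali changes, oxalate minus control mice, below 0 for 12 lists and above 0 for 7. EdgeR's quasi-likelihood test called no single gene, while DESeq2 called 12 higher and 14 lower and limma-voom 1 lower. The median difference between the alkali changes was -0.69 for tubular injury, -1.05 for macrophage and monocyte, -0.30 for T and NK cell, -0.61 for fibroblast and matrix, -1.09 for cytokine, -0.60 for NF-kB, -0.58 for complement, -0.32 for interferon, -0.45 for MHC class II, -0.16 for oxidative stress, -0.51 for cell cycle and -1.07 for immediate early genes. It was 0.25 for proximal tubule, 0.25 for thick ascending limb, 0.23 for distal convoluted tubule, 0.19 for intercalated cell, 0.19 for endothelial, 0.16 for tricarboxylic acid cycle and 0.49 for mitochondrially encoded genes. Camera called these 19 lists (adjusted p from 5.68e-12 to 0.0446). With an estimated correlation their adjusted p ran from 0.653 to 0.708, and fry gave 0.419 to 0.714, so neither held any of them. The proximal tubule call was lost without untreated oxalate library 40 (0.483) or alkali-treated oxalate library 2 (0.302), the T and NK cell call without untreated control library 26 (0.0532) or those same libraries (0.0585 and 0.367), the MHC class II call without alkali-treated oxalate library 2 (0.126) and the tricarboxylic acid cycle call without untreated oxalate library 40 (0.0875). The distal convoluted tubule call was lost without untreated oxalate library 12 (0.0599) or 40 (0.0585) or alkali-treated oxalate library 5 (0.0566). The oxidative stress call was lost without any of 12 libraries (untreated controls 13, 26 and 9, alkali-treated controls 27, 37 and 7, untreated oxalate 12, 3, 32 and 39, alkali-treated oxalate 33 and 5; 0.0581 to 0.35), and the mitochondrially encoded call without any of 9 (untreated controls 13 and 35, alkali-treated controls 4 and 7, untreated oxalate 12 and 40, alkali-treated oxalate 2, 33 and 8; 0.0529 to 0.157).

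Alkali-treated oxalate library 2 lay nearer the control libraries than any other oxalate library, with low injury and immune genes. A control library under an oxalate label was argued against: this library lay above all 10 controls in 67.2% of the 500 genes most raised by oxalate, while no control library lay above the other 9 in more than 25%. The other alkali-treated oxalate libraries did so in 90% to 97.8%. The untreated oxalate libraries did so in 94.4% to 99.2%, but their values had helped to choose these genes. A lower amount of injury in library 2 therefore stays open, and milder disease and a better response to alkali may both produce it.

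Alkali changes in oxalate mice ran against the oxalate changes for genes such as Havcr1, Vcam1 and Ccl2. Chance values of the shared untreated oxalate libraries as the whole cause were argued against, since the covariance was negative in 20 of 20 splits in which the comparisons shared no library. It ran from -0.379 to -0.0201. The splits reuse the same untreated oxalate, control and alkali-treated libraries, so they are not 20 separate tests. Uneven injury by chance between 2 groups of 5 mice stays open. The exact permutation p of the tubular injury score was 0.0397 unadjusted, which had been the test at the start, and 0.0979 after adjustment over all score tests, a form chosen after the unadjusted p was seen. An effect of alkali on injury is the biological explanation that the design names, and it may hold together with uneven injury.

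Among genes called for alkali in oxalate mice but not for oxalate was Insc, a spindle orientation gene. Its alkali change was 1.38 ± 0.27 in oxalate and 0.70 ± 0.27 in control mice. Its oxalate change was -0.57 (quasi-likelihood test, adjusted p = 0.0886), so a missed call does not show that oxalate left a gene unchanged. Genes of this kind tended to move the same way in control mice. Over these 158 genes the correlation of mean log2 CPM differences was 0.813. The exact one-sided permutation p over all splits of the 10 control libraries into groups of 5 was 0.0238, but the 158 genes had been chosen with the untreated controls, which builds part of the correlation in, so this p decides nothing. With the genes chosen again in each of 100 splits, the other splits had a median correlation of 0.328. A correlation as high as the real one came in a share of 0.04 of the splits (highest other 0.895) and a percentage of genes with the same sign as high as the real 86.7% in a share of 0.05 (highest other 93.1%), the real split counted in both. A chance split of the control libraries therefore stays open. TMM scaling as the whole cause was tested by scaling with total counts. A correlation hardly responds to scaling, but the percentage of genes with the same sign can. It went from 85.4% to 80.4% under total-count scaling, within the 75.9% to 89.2% of fits without 1 library and above the median of 58.2% in the other splits. That median is an unlike measure, since those splits chose the genes again and used mean log2 CPM differences. That scaling moved the median of all genes only from 0.006 to -0.050 in oxalate and from -0.002 to 0.033 in control mice. Few signs could therefore flip. The shift was small beside the 158 genes' median control change of 0.12, taken in the direction of their change in oxalate mice. The outcome was thus nearly fixed, and the test does not decide on scaling as a cause. It shows only that these genes kept most of their shared signs under total counts. For adipose RNA, the correlation of fitted changes was 0.797 with all libraries and 0.779 without the 6 adipose-rich libraries. This lay above 0.41, a limit set from the known full value, so the correlation over these genes does not need those libraries. But the genes were chosen with them, and the other untreated controls stay in both the choice and the correlation. Adipose RNA is therefore not excluded. Without each library in turn this correlation ran from 0.574 (without untreated control library 19) to 0.881 (without alkali-treated control library 27). An alkali response that needs no crystals is a candidate explanation, formed and tested on the same data.

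The number of genes called was compared with 100 splits of the libraries for each comparison. For oxalate without alkali only the real split (1 of 100) called 7630 genes, and the highest other called 3960. Chance was argued against, though 100 splits cannot exclude it. For oxalate on alkali 2 of 100 splits, the real one included, called at least 6237. That share argued against chance but cannot exclude it, since the other of these splits called more genes than the real one. This other split gave the highest count, 6914, and exchanges alkali-treated oxalate library 2 for alkali-treated control library 4. For alkali in oxalate mice 7 of 100 splits called at least 630 genes, so chance was not excluded. The highest other, 2990, several times the real count, set untreated oxalate libraries 12, 3 and 40 with alkali-treated oxalate libraries 33 and 8. On the leading principal component, which separates oxalate from control libraries, these lay highest (52.0 to 102), and the remaining oxalate libraries lay at -17.0 to 46.5. A grouping of the oxalate libraries along this component thus called more genes than the grouping by alkali. For alkali in control mice and for the interaction the real count was 0, which every split reaches (100 of 100, highest others 0 and 14), so the splits decide nothing there.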

How the results depend on the processing

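Total-count scaling and the fit without the 6 libraries with Adipoq above 1 CPM were chosen after the data were seen. Each count for oxalate without alkali stayed within 1.5 times under all alternatives but total-count scaling (7498 higher, 1308 lower). Lower genes outnumbered higher ones without a filter (49.8% higher) and without the 6 libraries (49.6%). Total-count scaling also gave 5645 and 953 on alkali. DESeq2 called 486 higher and 717 lower for alkali in oxalate mice, 3 higher in controls, 12 and 14 for the interaction, and 857 opposite to oxalate and 7 the same way. Limma-voom gave 4217 lower for oxalate on alkali, 1 lower for the interaction and 61 the same way. Without a filter 218 were lower for alkali in oxalate mice. A fit of only the groups compared gave 15 and 14, with 22 opposite and 0 the same way, and 52 of 58 named calls were lost there (adjusted p from 0.052 to 0.241). Without the 6 libraries alkali gave 467 and 796 in oxalate mice, oxalate on alkali 2263 and 956 (70.3% higher), the interaction 1 higher (Nccrp1), and 1095 were opposite and 1 the same way. With untreated oxalate libraries split, opposite calls had a minimum of 2, a median of 78.5 and a maximum of 1456, and same-way calls 0, 0.5 and 7. The cause was not tested for these changes. The fit of only the groups compared has fewer libraries and also its own estimate of the spread, which the main fit shares over all 4 groups. Untreated and alkali-treated oxalate libraries had an SD of 28.9 and 33.4 on the leading principal component, against 10.4 and 9.40 in controls. In that fit 2074 genes were at unadjusted p under 0.05 for alkali in oxalate mice, against 3156 in the main fit. For alkali in control mice 742 were, against 389.

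Without each library in turn, oxalate without alkali gave 3332 to 4231 higher and 3114 to 4351 lower, and oxalate on alkali 2842 to 4293 and 1540 to 3634. Alkali in oxalate mice gave 93 to 442 and 92 to 718, alkali in controls 0 to 1 and 0 to 0, the interaction 0 to 2 and 0 to 1. Opposite calls ran from 135 to 978 and same-way calls from 1 to 47. Camera's direction reversed without untreated oxalate library 40 for oxidative phosphorylation under alkali in oxalate mice (adjusted p = 0.000291, the list being uncalled with all libraries), the tricarboxylic acid cycle there (0.895) and oxidative phosphorylation in the interaction (0.0216); the cause was not tested. Over all libraries left out, adjusted p ran from 0.000291 to 0.802, from 0.000496 to 0.895 and from 0.00235 to 0.998 for these. With the median in place of the mean over members, 2 list scores reversed, oxidative stress for oxalate without alkali (-0.69) and calcium, phosphate and oxalate handling for oxalate on alkali (-0.017), since members of these lists go both ways. Of 828 pairs of a named gene and a comparison, 138 uncalled values changed sign in an alternative, and 127 had no value in one. No paired analysis was possible because the groups share no replicate number. Chi-square per degree of freedom between libraries of a group ran from 9.09 to 217, so over all genes the spread between libraries exceeded counting noise.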

Other observations

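The shared alkali test with its splits, and the choice of the genes in this part that lie outside the fixed rules (Fam25c, F2, Bco1, Ttc22, Sema4a, Olfm4 and Mogat2), were made after the results were seen.

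Among genes that respond to acid load 3 of the ammoniagenesis and acid-base list were called under alkali in oxalate mice, in both directions, and camera did not call the list (adjusted p = 0.266). Slc38a3 and Pck1, which proximal tubules raise to make ammonia and glucose from glutamine in acidosis, were lower with alkali in oxalate mice (-1.34 ± 0.21 and -1.57 ± 0.26, n = 5 per group), while neither had been raised by oxalate (0.44 ± 0.20 and -0.23 ± 0.26, not called, although Slc38a3 was called without untreated control library 19, adjusted p = 0.0354, or untreated oxalate library 32, adjusted p = 0.0429). In control mice the same genes were at -0.46 ± 0.20 and -0.53 ± 0.26, not called. Slc4a1 and Aqp6, both of acid-secreting intercalated cells, were higher with alkali in oxalate mice (0.95 ± 0.16 and 0.67 ± 0.17), and the call of Aqp6 was lost without untreated oxalate library 12 or 3 or alkali-treated oxalate library 33, 5 or 8 (adjusted p from 0.0535 to 0.099). Slc26a4, the bicarbonate exchanger of the other intercalated cells, was at 0.34 ± 0.13 and Rhcg, an ammonia channel, at 0.21 ± 0.12, neither called. Glud1 (-0.18 ± 0.11) was not called either, and the called genes of the ammoniagenesis and acid-base list are Slc4a1, Slc38a3 and Pck1.

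Several enzyme genes of lipid and foreign-compound metabolism were among those called for alkali in oxalate mice, and no list tested them all together. Cyp4a14 and Cyp4a10 belong to the fatty acid oxidation list, which camera did not call. Gsta2 and Gstm1 belong to the oxidative stress list, whose camera call held neither with an estimated correlation nor with fry. Cyp4a14 and Cyp4a10, both PPAR-alpha targets, were lower in oxalate mice (-4.64 ± 0.91 and -1.28 ± 0.30, the latter call lost without untreated oxalate library 12, 3 or 39 or alkali-treated oxalate library 30, adjusted p from 0.0512 to 0.066), Ces1g and Ces2h were higher (2.39 ± 0.31 and 1.21 ± 0.21), and Gsta2 and Gstm1 were lower (-1.30 ± 0.13 and -0.45 ± 0.10). The call of Gstm1 was lost without untreated oxalate library 12 (adjusted p = 0.0525). Aldh1a1, raised by oxalate (1.82 ± 0.20), was lower with alkali (-1.22 ± 0.20). A quasi-likelihood fit of the oxalate libraries alone kept the calls of Cyp4a14, Ces1g and Gsta2. It lost those of Ces2h, Cyp4a10, Gstm1 and Aldh1a1 (adjusted p = 0.0918, 0.12, 0.168 and 0.0608). F2 was lowered by oxalate (-2.39) and raised by alkali in oxalate mice (3.77 ± 0.32, adjusted p = 2.11e-06). In controls it was at 1.25 ± 0.27, not called by edgeR but called by the DESeq2 Wald test (adjusted p = 0.0414).

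The alkali changes of both backgrounds were compared over the 630 genes called in oxalate mice, as a hypothesis that alkali has effects that need no crystals. Fam25c was at -1.28 ± 0.20 in oxalate mice and -0.96 ± 0.20 in control mice, Bco1, of carotenoid cleavage, at 0.96 ± 0.17 and 0.70 ± 0.17, Ttc22 at 1.20 ± 0.16 and 0.60 ± 0.16, Sema4a at 0.37 ± 0.08 and 0.27 ± 0.08, Olfm4 at -0.65 ± 0.11 and -0.35 ± 0.11, and Mogat2, of fat re-esterification, at -1.98 ± 0.29 and -0.76 ± 0.29, none called in controls. Of the 630 genes, 449 had the same sign in control mice (71.3%, exact one-sided permutation p = 0.0714). Of the 469 opposite to oxalate 66.3% did (exact one-sided permutation p = 0.187). Among the 630, 59 against 1 were at unadjusted p under 0.05 in control mice in the same against the other direction. Of these, 38 against 0 came from the 158 genes not called for oxalate, whose choice used the untreated controls. The 469 genes opposite to oxalate gave 20 against 1. Genes are not independent replicates, so these counts are no test. The correlation across the 630 genes was 0.550 (exact one-sided permutation p = 0.0278, highest other split 0.610). For the 469 genes opposite to oxalate it was 0.472 (exact p = 0.0595), and for the 158 not called for oxalate it was 0.813, part of which the choice of these genes builds in, since splits that chose them again had a median of 0.328. Over all genes the correlation was 0.0655, against 0.000563 in simulated unchanged groups, which share no library between these comparisons. The simulated groups held little variation that genes share between libraries, so this gap decides nothing. The p-values were not adjusted over the 4 categories, and the percentage of genes with the same sign among those not called for oxalate was as high in a share of 0.05 of the splits, so a shared alkali response is not shown.

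Other measures per group gave no comparison of their own. Mitochondrially encoded transcripts took 10.1% ± 0.55, 9.73% ± 0.60, 8.55% ± 1.08 and 11.5% ± 2.24 (SD, n = 5) of the counts in untreated controls, alkali-treated controls, untreated oxalate and alkali-treated oxalate libraries. Adipoq exceeded 1 CPM in 6 libraries, at 29.7, 20.1, 2.90, 18.0, 3.11 and 35.4 CPM in untreated controls 26 and 9, alkali-treated controls 1 and 4, untreated oxalate 32 and alkali-treated oxalate 33. The Y-linked gene Ddx3y was at 36.9 CPM or more in all 20 libraries.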
